A study of Homo sapiens with 2 samples.

How the data were processed

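Total RNA of 2 preparations labelled as HLE B-3 cells, 1 carrying an hGSTA4 construct and 1 the empty pTarget plasmid, had been hybridised to 1 single-colour array each. The probe table given with the data names the platform as Affymetrix HG-U133 Plus 2.0. The deposited values are probe-set signal intensities on a linear scale, all above 0. Software, background correction and summary method are not given in the sources used here. After leaving out the lowest and highest 2% of probe sets, the mean of the intensities as deposited was 500.1 on both arrays, so each array appears to have been scaled to a target of 500; this is read from the values. No detection calls were used. Scanner files were not analysed here.

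Of 54675 probe sets, 62 are controls. Of the others, 41091 named 1 gene in the platform annotation, 1801 named several and 11721 had no entry; the last 2 kinds entered no comparison. Symbols were updated through the gene ID for 41037 probe sets with the annotation of assembly GRCh38.p14, used for names and for the order of neighbouring genes only. Symbols in the gene lists were matched through the same tables.

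The difference of a gene is log2 of its signal on the array labelled hGSTA4 minus that on the empty-vector array, shifted by 0.08 so that the median over non-control probe sets above the floor on both arrays is 0. No pseudocount was used. The floor of each array is the median of its non-control probe sets, 122.3 on the array labelled hGSTA4 and 123.7 on the other. A gene is "bright" at or above the 75th percentile, 442.9 and 494.5. Each gene is represented by the probe set with the highest mean log2 signal. A gene bright on 1 array and under the floor on the other is given as "at least N-fold", the bright signal against the higher of the floor and the dim signal, with the same centring. Genes at or above 2-fold were counted over genes above the floor on both arrays.

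A list's median difference was placed among the medians of 10000 random lists of as many genes, drawn with replacement within 20 bins of mean signal. Genes bright on 1 array only entered a list's median in a second version, at their bound. A list was called when its percentile was under 2.5 or over 97.5 and it had at least 5 measured members. Genes of a pathway vary together, so these percentiles are narrower than a test with replicates would give. The groups hold 1 array each; no test across samples, paired fit or left-out replicate was possible.

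Named genes followed a rule set, like the lists and all alternatives but the centring on control probe sets, before the data were examined. They are GSTA4; the 12 largest differences in each direction among genes bright on at least 1 array whose other measured probe sets all had the same sign; and the 5 largest lower bounds in each direction. Added to these are the 4 members furthest in the direction of each called list, and the 3 largest of the glutathione, aldehyde, NRF2, lens, adhesion, p53, cell cycle and apoptosis lists, in both cases among members above the floor on both arrays. Besides those flagged below, MYL4, FN1, MET, CXCL8, CFLAR, COL1A1, KRT8 and H2BC5 were read on probe sets whose IDs mark possible cross-hybridisation.

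The scripts were tested on simulated data: the empty-vector signals were copied, multiplied by 1.3 and given log2 noise of SD 0.3, and 200 genes were changed. Of the changed genes above the floor, 100% at a log2 change of 2 and 98% at 1.5 came out at 2-fold or more, in both directions, among 12300 genes compared, with 7 unchanged genes called. A raised and a lowered list were both called, and 1 of 45 unchanged lists was. This noise is assumed, since the arrays have no replicates. Alternatives were other scalings (none, quantile, loess with a span of 0.3, control probe sets), other floors, an added constant and other choices of probe set. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.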

Results

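The series compared 2 preparations of total RNA, both labelled as coming from HLE B-3, a human lens epithelial cell line, on 1 oligonucleotide array each. One was labelled as cells carrying a construct that expresses recombinant hGSTA4-4, the glutathione transferase encoded by GSTA4, which conjugates the lipid peroxidation product 4-hydroxynonenal. The other was labelled as cells carrying the same plasmid, pTarget, without an insert. The comparison asks which transcripts differ when hGSTA4-4 is expressed. Each array reported 54675 probe sets, of which 41091 named exactly 1 gene, giving 19775 genes. Signals ran from 0.1 to 59583.9 on the array labelled hGSTA4 and from 0.2 to 53773.8 on the empty-vector array. With 1 array per group no difference below has a replicate check, no p-value can be given, and every value describes these 2 arrays. The number of arrays limits the precision. The values carry no genome positions, so genes are named by symbol and probe set.

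The transfected gene was lower, not higher, on the array that carries its name. The brightest GSTA4 probe set read 190.0 on the array labelled hGSTA4 and 1113.1 on the empty-vector array, a 6.20-fold lower signal and a log2 difference of -2.63, or -2.04 with the floor value added before log2. The other GSTA4 probe set read 12 and 54.9, both under the measurement floor. Whether either probe set lies within the recombinant part of the construct is not given in the sources used here, so this does not settle whether the construct was expressed. Since the named gene went against the label, the array is called "the array labelled hGSTA4" throughout, and every direction below rests on that label.

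The profiles of the arrays lay far apart. Embryonic globins, tumour-testis antigens and blood-lineage regulators were among the genes with the largest differences toward the array labelled hGSTA4, and matrix, adhesion and antigen presentation genes among those with the largest differences toward the empty-vector array. Of 10861 genes above the floor on both arrays, 1245 were at least 2-fold higher and 1578 at least 2-fold lower on the array labelled hGSTA4. The remaining 8038 lay within 2-fold. Differences of 16-fold or more were seen for 34 genes in the higher and 70 in the lower direction. A further 260 genes were bright on the array labelled hGSTA4 and under the floor on the other, and 472 were bright on the empty-vector array and under the floor on the first. Log2 signals of the genes above the floor correlated across genes with a Pearson r of 0.81; genes are not independent replicates. Centring on bacterial and phage control probe sets in place of the median gene gave 573 higher and 2736 lower genes, so that 17.3% rather than 44.1% of the 2-fold differences were in the higher direction. Quantile normalization gave 1528 higher and 1362 lower genes, with 52.9% in the higher direction, so which direction held more genes depended on the scaling.

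Among genes under the floor on the empty-vector array, the largest lower bounds belonged to HBE1 and HBZ, the embryonic epsilon and zeta globin chains. HBE1 read 45616.2 against 85.1, at least 348-fold higher on the array labelled hGSTA4. HBZ read 41123.6 against 8.2, at least 314-fold higher. The tumour antigen genes PRAME and MAGEA6 followed, at least 210-fold and at least 146-fold higher. MAGEA6, like SSX1 below, was read on a probe set whose ID marks possible cross-hybridisation. PRKCB, a protein kinase C isoform abundant in blood cells, was at least 120-fold higher. Among genes measured on both arrays, KCNH2, a potassium channel, led with a 67.0-fold higher signal. MYB, a transcription factor of blood progenitors, was 62.9-fold higher and KLF1, the erythroid Krüppel-like factor, 37.1-fold higher. SRGN, the proteoglycan of haematopoietic granules, was 54.5-fold higher. DLK1 was 58.6-fold, HIC2 45.0-fold, VAMP8 42.2-fold, SSX1 42.1-fold, DDIT4 41.8-fold, SDF2L1 31.4-fold, SOCS2 30.4-fold and MYL4 30.0-fold higher. The dim signals lay close to the floor, at 136.4 for MYB and 145.2 for KLF1, and the sizes depend on them: with the floor value added before log2, MYB was 34.0-fold and KLF1 20.8-fold higher, and the 12 genes ranged from 18.2-fold to 42.7-fold.

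On the opposite side, TGFBI, a secreted matrix protein, read 34386.6 on the empty-vector array and 39.4 on the array labelled hGSTA4, at least 298-fold lower on the latter. The genes BEX3, DKK3, CRIM1 and C12orf75 were at least 140-fold, 135-fold, 129-fold and 117-fold lower. Of genes measured on both arrays, S100A6, a calcium-binding protein, had the largest difference in this direction, with 301.3 against 37544.3, a 132-fold lower signal. HLA-B, a heavy chain of MHC class I, was 120-fold lower, on a probe set whose ID marks possible cross-hybridisation. The secreted proteins FSTL1 and CCN1 were 117-fold and 107-fold lower. CAV1, the caveolar coat protein, was 77.3-fold lower and CD44, the hyaluronan receptor, 69.7-fold lower. BEX1, BASP1, COL5A2, MARCKS, UCHL1 and PFN2 were between 61.6-fold and 87.3-fold lower. With the floor value added before log2, the 12 genes ranged from 38.5-fold to 92.5-fold lower. Probe sets of 1 gene did not always give the same size: the 2 measured UCHL1 probe sets differed by -6.14 and -0.24 on the log2 scale, and the 7 of CD44 ranged from -6.12 to -1.34.

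**Figure D1:**
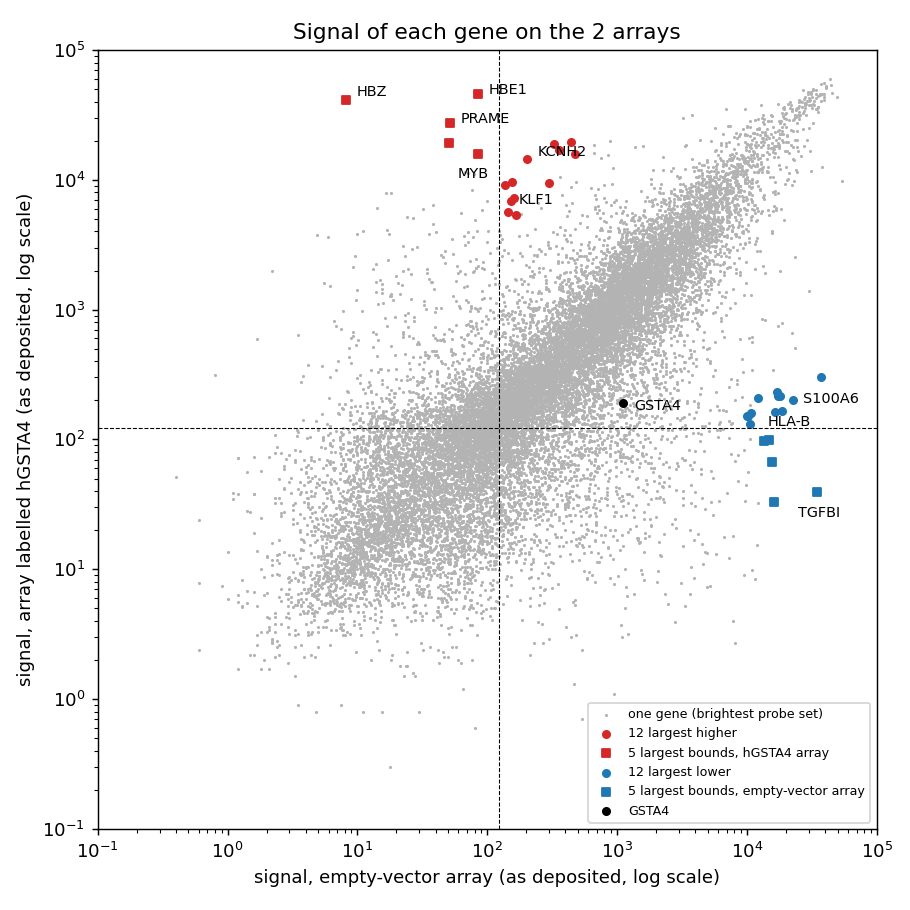
Signal of each of 19775 genes on the empty-vector array (horizontal, log scale) and on the array labelled hGSTA4 (vertical, log scale), as deposited, 1 point per gene and 1 array per axis. Dashed lines mark the floors of 123.7 and 122.3, squares mark the 5 genes with the largest bounds in each direction, round coloured points the 12 largest differences, and GSTA4 lies below the main cloud at 190.0 against 1113.1.

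Technical measures put a scale beside these sizes. The 38 bacterial and phage control probe sets with a signal of at least 500 on both arrays differed by a mean of 0.45 ± 0.24 on the log2 scale (SD over probe sets) after centring, with a range of -0.03 to 1.07. Among 4857 genes with at least 2 measured probe sets, the 2 brightest went the same way in 74.8%, and in 91.0% of the 1225 whose brightest differed at least 2-fold. Their differences correlated across genes with a Pearson r of 0.74. The 3′ to 5′ signal ratio was 1.63 against 1.15 for ACTB and 0.95 against 0.96 for GAPDH, on the array labelled hGSTA4 and the empty-vector array. The 12 measured reference genes had a median difference of 0.17, and 10 of them lay within 2-fold.

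Gene groups were then described through 54 lists fixed before the data were examined. Of the 47 lists with at least 5 measured members, 6 had a median above and 18 a median below the central 95% of random lists matched on signal, where about 1.2 would be on each side for random lists. The percentiles below are positions among 10000 such random lists, not p-values. Medians and counts cover genes above the floor on both arrays. With genes bright on 1 array only entered at their bound, none of the 24 called lists changed sign, and the medians of the 17 that hold such genes moved by -1.57 to 0.01.

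Lens and eye development genes were lower on the array labelled hGSTA4. The median difference of the 5 measured members was -4.13 (percentile 0), and 4 of the 5 were at least 2-fold lower. PAX6, the eye-field transcription factor, read 292.8 against 7571.5, a 27.4-fold lower signal. The transcription factors TFAP2A and SIX3 were 32.6-fold and 7.93-fold lower, and the small heat shock crystallin CRYAB was 17.5-fold lower. In the same list GJA1 was bright only on the empty-vector array, at least 89.0-fold lower, and MEIS1 only on the array labelled hGSTA4, at least 3.80-fold higher (both named after their values were seen). With no floor the lens list lay at percentile 3.56, within the random range. None of the lens fibre proteins was above the floor on both arrays. Of 13 leukocyte markers on the array 1 was above the floor on both, too few for a percentile, and 6 were under the floor on the array labelled hGSTA4, among them CD3E, CD4 and CD14. Of the same list, 3 genes were bright only on the array labelled hGSTA4: LYZ at least 60.7-fold, CD3D at least 15.7-fold and PTPRC at least 5.18-fold higher (named after their values were seen). Simple epithelial genes had a median of 0.85 (percentile 98.5), with KRT19 13.0-fold, EPCAM 12.8-fold and KRT8 3.02-fold higher, and MUC1 at a log2 difference of 0.85. This list lay within the random range with no floor (percentile 96.8) and with medians over probe sets (percentile 88.2). Fibroblast markers had a median of -1.82 (percentile 0.08), with THY1 11.1-fold, COL1A1 4.88-fold, S100A4 3.53-fold and COL1A2 2.01-fold lower. Of the tissue-specific genes listed to check the background, HBE1 was bright on the array labelled hGSTA4, 2 of 6 measured were at least 2-fold higher, and the median was 0.29 (percentile 84.1). Keratinocyte, endothelial and pigment cell lists also had under 5 measured members.

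Matrix and adhesion genes were lower as groups on the same array, the one on which HBE1 was at least 348-fold higher and PAX6 27.4-fold lower. Of 10 measured collagens 6 were at least 2-fold lower and none higher, with a median of -1.65 (percentile 0). COL5A2 was 84.6-fold, COL4A2 29.9-fold, COL6A1 7.89-fold and COL4A5 5.93-fold lower. Among collagens bright on 1 array only, 4 were bright on the empty-vector array, and COL15A1 on the array labelled hGSTA4, at least 4.22-fold higher (named after its value was seen). Of 12 laminins and other matrix glycoproteins 7 were at least 2-fold lower and none higher, with a median of -1.73 (percentile 0). FN1, VCAN, SPARC and LAMB1 were 25.1-fold, 18.5-fold, 16.4-fold and 10.9-fold lower. One of the 5 measured FN1 probe sets did not follow, with a difference of 0.06, and the glycoprotein list lay within the random range without probe sets marked as shared (percentile 7.85). Of 6 measured integrins 4 were lower and none higher, with a median of -1.22 (percentile 0.14), ITGAV by 6.37-fold, ITGB1 by 2.61-fold, ITGA5 by 2.44-fold and ITGB5 by 2.23-fold. Mesenchymal transition genes had a median of -1.77 (percentile 0), and 7 of 9 were lower, TWIST2 by 4.71-fold. Actin and smooth muscle proteins had a median of -1.0 (percentile 0.01), with 9 of 19 lower and none higher: TAGLN by 56.0-fold, ACTA2 by 10.3-fold, TPM1 by 9.72-fold and TPM4 by 7.38-fold. Cadherins, desmosomes and tight junctions had a median of -0.45 (percentile 5.95), within the random range; OCLN was 8.0-fold and PCDH9 4.09-fold lower, and JUP 6.76-fold higher. Bright only on the empty-vector array were 5 more of this list, CLDN1, DSP, CDH2, DSC3 and CDH11, at least 6.13-fold to 29.0-fold lower (named after their values were seen). Matrix proteases and inhibitors also lay within it, at -0.62 (percentile 5.77). With genes bright on 1 array only at their bound, the medians of these lists were -1.62 and -2.65. No connexin and 1 insulin-like growth factor binding protein were measured on both arrays; 2 and 5 of these families were bright only on the empty-vector array.

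Growth factor receptors, immediate early genes and the TGF-beta list were lower beside the same difference in HBE1, while 5 other signalling lists were within the random range. Of 19 growth factor receptors 10 were at least 2-fold lower and 2 higher, with a median of -1.51 (percentile 0). EGFR, the epidermal growth factor receptor, was 48.0-fold lower, although its 3 measured probe sets ranged from -5.58 to -0.28. The receptor tyrosine kinases AXL, EPHA2 and MET were 19.0-fold, 14.9-fold and 14.2-fold lower. Immediate early genes had a median of -1.40 (percentile 0), with 8 of 14 lower and 1 higher; FOSL1, IER3, MAFF and EGR1 differed by -3.41, -3.32, -2.74 and -2.08 on the log2 scale. TGF-beta pathway genes had a median of -0.57 (percentile 1.02), with 6 of 19 lower and 2 higher, TGFBR2 by 14.2-fold, SMAD7 by 6.29-fold, ID3 by 4.95-fold and SMAD3 by 2.92-fold; 1 of the 3 measured SMAD3 probe sets gave 0.34. Centring on the control probe sets put 10 of the 19 at least 2-fold lower. Growth factors at -0.37 (percentile 9.11), MAP kinases and phosphatases at -0.11 (percentile 35.2), protein kinase C isoforms at -0.40 (percentile 11), the Wnt pathway at -0.55 (percentile 7.78), the Notch pathway at 0.22 (percentile 75.3) and HOX genes at 0.20 (percentile 79.8) lay within the random range. These percentiles leave out genes bright on 1 array only; with those at their bound, the medians were -2.86 for the Wnt pathway, -1.43 for growth factors, -0.41 for MAP kinases, -0.06 for protein kinase C, 0.08 for Notch and 1.16 for HOX genes.

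Antigen presentation, interferon and inflammatory genes were lower on the array with the bright globin signals. Of 11 measured genes of MHC class I and antigen presentation 9 were at least 2-fold lower and none higher, with a median of -2.24 (percentile 0). HLA-C was 49.1-fold, PSMB9 12.9-fold and HLA-F 12.5-fold lower. The HLA-C and HLA-F values are from probe sets marked for cross-hybridisation. Interferon response genes had a median of -1.27 (percentile 0), with 12 of 17 lower and 2 higher; IFIT3, IFI6, IFI27 and OASL were 26.6-fold, 12-fold, 9.17-fold and 6.70-fold lower. That median turned to 0.26 (percentile 78.3) when the floor was raised to the 75th percentile. Inflammatory cytokines and NF-kB targets had a median of -0.68 (percentile 1.39), with 6 of 12 lower and 1 higher, CXCL8 by 6.60-fold, NFKBIA by 3.82-fold, CSF1 by 2.36-fold and IL6 by 2.13-fold. This list lay within the random range with the floor value added before log2 (percentile 9.61) and without probe sets marked as shared (percentile 21.5). Prostaglandin and arachidonate enzymes lay at -0.24 (percentile 26.6).

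The pathways closest to hGSTA4-4 itself lay within the random range as groups, counting genes above the floor on both arrays. GSTA4 itself was lower on the array labelled hGSTA4, so these medians show neither an effect of hGSTA4-4 nor its absence. Other glutathione transferases had a median of -0.02 (percentile 34.8), with 3 of 13 at least 2-fold higher and 2 lower. GSTM3 was 7.63-fold lower, MGST2 3.18-fold higher and GSTO1 2.63-fold higher. Glutathione synthesis and redox genes had a median of 0.33 (percentile 84.2); GPX3 was 5.86-fold lower, and GSR and GPX4 were 2.16-fold and 2.02-fold higher. This list also held 5 genes bright on 1 array only, named after their values were seen: GPX1, GPX8 and GPX7 were at least 95.4-fold, 54.2-fold and 5.71-fold lower, and CHAC1 and OPLAH at least 7.49-fold and 4.04-fold higher. With these at their bound the median was 0.29. Genes of aldehyde and hydroxynonenal disposal had a median of -0.35 (percentile 8.36). Within that list PTGR1, a reductase of hydroxynonenal, was 24.0-fold lower, while the aldo-keto reductases AKR1C1 and AKR1C2, near-identical paralogs on cross-hybridising probe sets, were each 18.7-fold higher. Bright only on the empty-vector array were ALDH7A1 and CBR1, at least 18.1-fold and 7.07-fold lower (named after their values were seen). NRF2 targets had a median of -0.05 (percentile 22.3), with 5 of 17 lower and 2 higher; HMOX1, NQO1 and EPHX1 were 5.99-fold, 4.49-fold and 3.58-fold lower. Superoxide, peroxide and thioredoxin enzymes had a median of 0.54 (percentile 96.2). Metallothioneins had the lowest median of all 47 lists, -4.91 (percentile 0), with 6 of 7 lower. MT1H was 59.9-fold, MT1X 49.3-fold, MT1E 30.8-fold and MT1G 30.1-fold lower, on probe sets marked for cross-hybridisation within this family. Heat shock proteins had a median of -0.34 (percentile 0.98), with 6 of 14 lower, among them HSPB2 by 4.23-fold, HSPB8 by 2.70-fold and HSPB1 by 2.23-fold. This list was called neither under quantile normalization (percentile 2.63) nor with medians over probe sets (percentile 5.24), and its median was 0.01 with the higher floor. The array on which HBE1 was bright is the one on which metallothioneins were dim.

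Cell cycle lists differed in direction by phase, again beside the difference in globin signals. Of 28 genes of G1/S and DNA replication 7 were at least 2-fold higher and 1 lower, with a median of 0.67 (percentile 99.97). CDC45, which lies in the replication helicase, was 8.62-fold higher, CCNE1 4.91-fold, CCND3 3.43-fold and ORC1 2.51-fold higher; CCND1, cyclin D1, was 10.5-fold lower. Centred on the control probe sets, this median was 0.21 with 3 genes at least 2-fold higher. Of 30 genes of G2/M and mitosis 7 were at least 2-fold lower and none higher, with a median of -0.47 (percentile 0.05). UBE2C was 33.6-fold, KIF23 3.94-fold, CDC25B 3.91-fold and AURKB 3.21-fold lower. Centred on the control probe sets, 14 of the 30 were at least 2-fold lower. Cell cycle inhibitors had a median of -0.97 (percentile 0.69), with 4 of 8 lower: CDKN2A by 33.4-fold, CDKN1A by 7.94-fold, CDKN1B by 2.38-fold and RB1 by 2.12-fold. In the same list CDKN1C, bright only on the array labelled hGSTA4, was at least 18.1-fold higher, and GADD45B, bright only on the other, at least 14.2-fold lower (both named after their values were seen). Without probe sets marked as shared, this list lay at percentile 4.41. Targets of p53 had a median of -1.05 (percentile 0.01), with 9 of 17 lower and none higher, DDB2 by 4.45-fold, TNFRSF10B by 4.06-fold and TP53I3 by 3.17-fold. With the floor at the 75th percentile, this list lay at percentile 12.5. Pro-apoptotic genes at -0.18 (percentile 20.3) and anti-apoptotic genes at -0.10 (percentile 28.9) lay within the random range. BAD was 5.23-fold lower and BID 3.16-fold higher, and BIRC2 and CFLAR were 2.61-fold and 2.43-fold lower and BCL2L2 2.06-fold higher. One of 3 BID and 2 of 11 CFLAR probe sets went the other way.

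Several biosynthetic groups were higher on the array labelled hGSTA4, where HBE1 was bright and PAX6 dim. The list named core histones, which also holds linker histones such as H1-2, had the highest median, 2.59 (percentile 100). Of its 9 measured genes 7 were at least 2-fold higher. The linker histone H1-2 was 22.7-fold higher, and H2AC6, H2BC5 and H2BC21 were 13.1-fold, 7.41-fold and 6.09-fold higher. Cholesterol synthesis genes had a median of 0.87 (percentile 99.97), with 8 of 18 higher and none lower. INSIG1, HMGCS1, MVD and SQLE were 6.80-fold, 5.46-fold, 5.14-fold and 4.92-fold higher. Unfolded protein response genes had a median of 0.86 (percentile 99.99), with 9 of 20 higher and none lower; ASNS, asparagine synthetase, was 27.0-fold, TRIB3 9.69-fold and DDIT3 4.07-fold higher. Oxidative phosphorylation genes had a median of 0.60 (percentile 99.6), with 6 of 26 higher and none lower, UQCRC2 by 2.90-fold, NDUFS3 by 2.60-fold, COX5A by 2.5-fold and ATP5PO by 2.28-fold. One of the 3 UQCRC2 probe sets gave -0.17. Centred on the control probe sets, the oxidative phosphorylation median was 0.15 with 1 gene at least 2-fold higher, and the cholesterol synthesis median 0.42 with 5 higher and 2 lower. Lists within the random range were fatty acid synthesis at 0.47 (percentile 93.9), peroxisome and fatty acid oxidation at 0.27 (percentile 85.0), hypoxia and glycolysis at 0.18 (percentile 52.8), ribosomal proteins at 0.52 (percentile 95.1) and the proteasome at 0.43 (percentile 90.3).

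**Figure D2:**
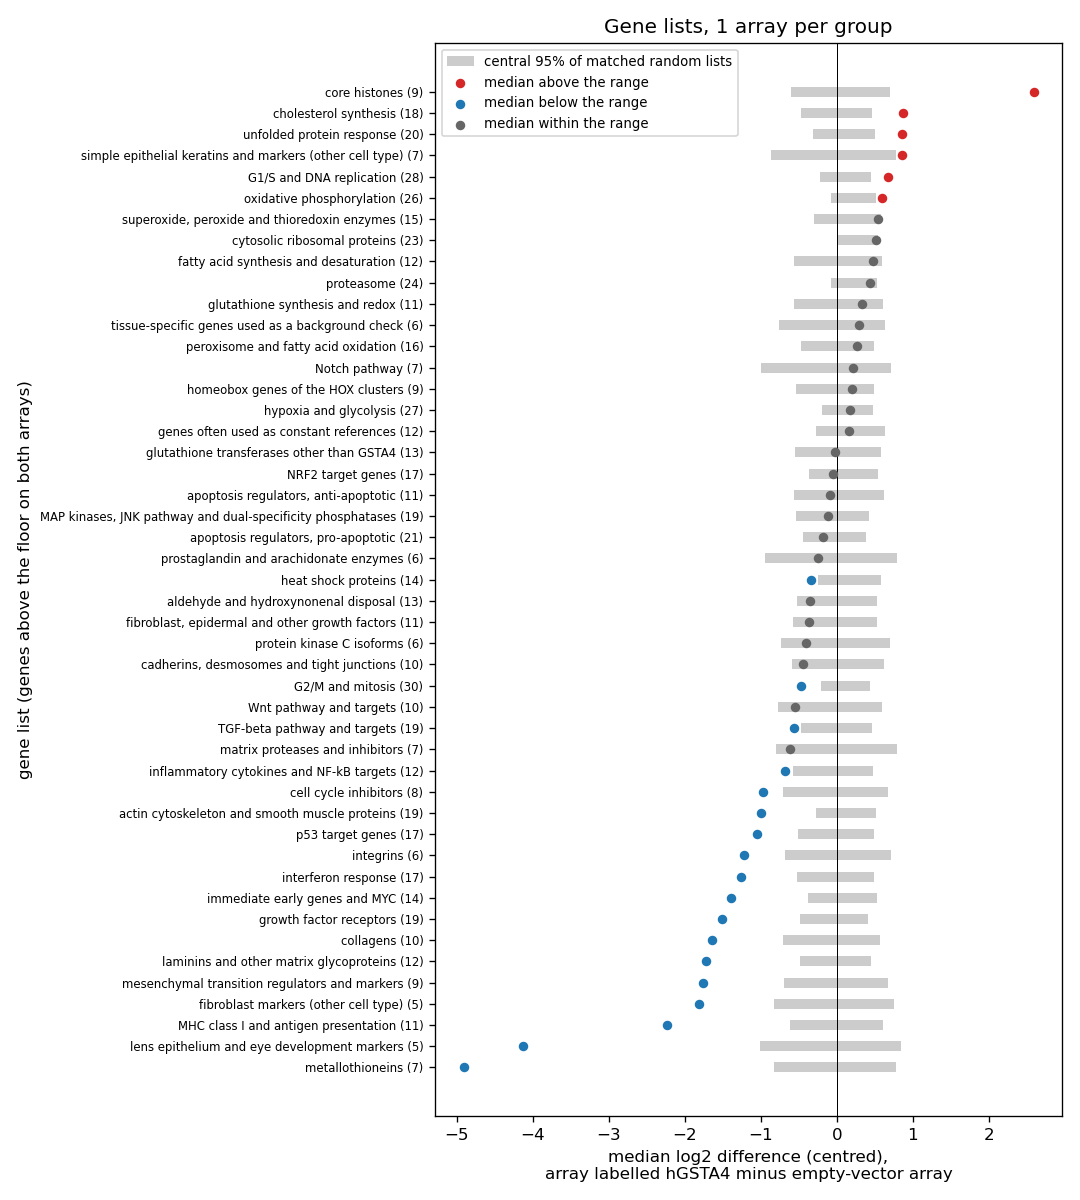
Median log2 difference of each of the 47 gene lists (horizontal, array labelled hGSTA4 minus empty-vector array, centred), with the number of measured genes in brackets after each name. Grey bars span the central 95% of 10000 matched random lists; 6 medians lie above their bar and 18 below, from core histones at 2.59 to metallothioneins at -4.91.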

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

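Among 13522 probe sets that named no gene or several genes and entered no comparison, 100 were bright on the array labelled hGSTA4 and under the floor on the empty-vector array, a signal outside the main measurement and above the level in the control. In the opposite direction there were 67.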

How the results depend on the processing

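All named genes measured on both arrays kept their direction under each scaling. They were chosen for large differences, so this says little about stability. Of the 24 list calls, loess kept 24 and quantile normalization 23, all but heat shock proteins. Without centring and with centring on the control probe sets every gene shifts alike, so list percentiles are fixed by construction and say nothing about stability. The median gene moved from 0.03 to 0.14 with quantile normalization, 0.11 as deposited and -0.42 with centring on the control probe sets, a scaling chosen after seeing the data. The last gave 573 higher and 2736 lower genes. With the floor value added before log2 there were 966 and 1229. A floor at the 25th percentile gave 2099 higher and 2644 lower genes, one at the 75th gave 622 and 725, and no floor gave 3585 and 4110. With the 25th percentile as floor, 91 genes were bright only on the array labelled hGSTA4 and 158 only on the other. The floor at the 75th percentile left 7 lists below the random range, since 9 of the 24 called lists then had under 5 measured members and 3 lost their call. The medians of heat shock proteins (0.0078) and interferon response (0.2592) turned positive there; the cause was not tested. Without probe sets marked as shared, 4 of the 24 had under 5 members and 3 lost their call. GSTA4 differed by -2.04 with the floor value added before log2, which draws values toward 0, and was not measured on both arrays with the higher floor. FN1 was 0.0643 without probe sets marked as shared, where another probe set stands for it. Of the values of single genes under alternatives, 1133 moved by under 1.5-fold, 59 by more and 1 (FN1) reversed. With 1 array per group no replicate could be left out. Signals near the floor limit the low genes, whose folds are lower bounds where a gene lies under it.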

Other observations

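Tests chosen only after the result was seen were those of scaling, of a mixture of cells and of exchanged labels, the count of genes from MLLT3 to TUSC1 and the scan of neighbouring genes on all chromosomes. The lists in this part were written after the first genes had been seen, but before any of their own members were looked at; the members named were chosen after their values were seen. Of 40 further erythroid genes, 28 had a probe set above the floor on either array; 20 of these were at least 2-fold higher on the array labelled hGSTA4 and none was 2-fold lower, while 18 were above the floor on the empty-vector array. GATA1 and TAL1, master regulators of the erythroid lineage, read 3846.3 against 17.4 and 4101.7 against 16.9. NFE2 read 5576.4 against 62.4, GFI1B 3941.4 against 40.1, and the haem enzyme UROD 18426.7 against 3385.5. Of 22 genes common to blood cells with a signal above the floor on either array, 11 were at least 2-fold higher and 1 lower (ARHGDIB). Their median was 1.07. Of 15 cancer-testis genes chosen in the same way, 11 were at least 2-fold higher and none lower, with a median of 3.36. LIN28B read 4540.3 against 37.9 and SSX3 3110.4 against 22.4. Of the blood-cell and cancer-testis genes, 12 and 2 were above the floor on the empty-vector array. In all 3 lists, a gene under that floor could not come out 2-fold lower. The counts of lower genes therefore rest on the others alone. All 3 medians lay at percentile 100 among matched random lists. A gene under that floor entered only through its signal on the array labelled hGSTA4. The medians and percentiles share this limit, most of all for the cancer-testis genes.

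The first pattern is the set of erythroid and cancer-testis genes bright on the array labelled hGSTA4 and dim on the other. A scaling difference between the arrays shifts every gene alike, so it cannot account for genes that differ strongly in both directions. The control probe sets had a mean absolute difference of 0.45, against bounds of 6.91 and more for the 5 leading genes. They add little, since this test was chosen after the result was seen. The test of a mixture of empty-vector cells with others included genes already seen to be low, so its outcome was known. Of 385 genes with a signal over 10000 on the empty-vector array, 31 kept under 5% of it on the other array. The 10th lowest kept 0.72%. This argues only against a mixture with 5% or more of unchanged empty-vector cells, and a smaller share stays open. RNA of an erythroid cell type met its prediction, with a median floored difference of 2.55 over the 28 erythroid genes, under the limit given above. A candidate explanation is therefore that the RNA on the array labelled hGSTA4 came from an erythroid cell line and not from HLE B-3 cells. A change of HLE B-3 cells under hGSTA4-4 remains open as untested, since group and array coincide.

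The second pattern is that neighbouring genes differed together. If the RNA came from K562, an erythroleukaemia line that carries a 9p21 deletion and an amplified BCR-ABL1 segment of 22q11, MTAP should be lost. It read 85.6, under the floor, against 479.1. Its floored difference of -2.05 passed the -2 set in advance by less than the centring shift of 0.08, so the call depends on the scaling. With MTAP under the floor, that value is a bound set by the floor and the empty-vector signal. From MLLT3 to TUSC1, 11 genes were above the floor on the empty-vector array. Of these 8 were under the floor on the other array, against 13.2% of all genes above it on the empty-vector array. The 8 included MTAP and both end genes of this run, which was chosen after the result was seen. CDKN2A (265.9 against 8384.2, on a probe set marked for cross-hybridisation), MIR31HG (374.8 against 614.6) and IFNA17 (523.8 against 303.4, higher) stayed above the floor. The floor is the array median and not a detection limit. Whether these genes are lost, and the extent of any loss, therefore stay open. On 22q11 the 14 genes between HIC2 and BCR not yet seen had a median of 0.80, at percentile 98.7 among windows of as many neighbours. This was short of the 99 set in advance. The windows compared include those of this region itself, with the genes already seen. Whether this lowered the percentile was not tested. BCR itself differed by 0.60, less than SNAP29 (2.92) and MED15 (2.40) on the far side of HIC2. Where a gain would begin, and where within BCR it would end, is not given in the sources used here. Those genes and the BCR probe set could therefore lie inside or outside a gain, so their values do not decide it. A gain cannot be told apart from a regional expression difference. In a scan made afterwards, the 14 highest of 13829 overlapping windows of 15 neighbours formed 1 run on chromosome 22, and so did the 14 highest without the 4 genes already seen, so this is 1 observation.

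The third pattern is GSTA4 itself, lower on the array that carries its name by a log2 difference of -2.63. An exchange of the 2 labels predicts this, but so does an erythroid line with little GSTA4, and these cannot be told apart with 1 array per group. Probe sets outside the recombinant part of the construct, whose position is not known here, would account for a missing excess. In the same cells, a lower signal would then need a lower level of the cells' own GSTA4, which was not tested. An exchange would not remove the first pattern, since 1 of the arrays labelled HLE B-3 would still carry the globin signals. If the second cell type is the source, the list differences of the report may describe 2 cell lines and not hGSTA4-4: PAX6, at 7571.5 on the empty-vector array and 292.8 on the other, bears on this in the same direction.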
